A study of Arabidopsis thaliana with 16 samples.

How the data were processed

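The data were RNA-seq libraries from dissected shoot apices of Arabidopsis thaliana, accession Col-0. Per the labels' protocols, plants were grown for 7 days on solid medium, moved to mock or drug plates, and cut free of roots, hypocotyl, cotyledons and true leaves, and RNA went into libraries made with Illumina's TruSeq RNA kit. The labels do not say whether the kit marked the strand of a transcript. FastQC, TopHat and the TAIR10 genome build are named, without versions, in the submitters' processing notes. The read counter, its settings and the gene annotation are not given in the sources used here.

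The authors deposited 1 table of 32678 gene models with 16 columns of read counts, which are whole numbers and not normalized, and these counts were the values tested. The authors deposited RPKM for the same models and samples. In 13343 gene models checked, RPKM scaled as the count divided by gene length and by the library's total in the table, with a largest relative deviation of 9.6e-10, so RPKM held the same information as the counts and was not tested. No RPKM was given for 34 models, and 7569 models had a count of 0 in all 16 libraries. Each column matched 1 sample by its title. The total per library ran from 6746970 to 18265411 counts.

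Groups came from the sample titles, with 2 libraries in each of 8 groups. Counts were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F-test after TMM scaling and filterByExpr, in 1 fit of all 16 libraries with a mean per group. The filter kept 19317 gene models, which held at least 99.93% of the counts of every library. The fit had 8 residual degrees of freedom, 5.66 prior degrees of freedom and a biological coefficient of variation of 0.098. P-values were 2-sided, and a gene passed at a Benjamini-Hochberg adjusted p below 0.05. Levels are CPM on the TMM scale, with the SD of 2 libraries. The SE of a log2 fold change was back-calculated as its absolute value divided by the square root of the F statistic. It is approximate, and least reliable for fold changes near 0 or genes with few reads. Counting error sets a limit for genes with few reads. For a gene with no count in a group, the fold was computed against a floor of 3 counts per library. That floor covers counting error only.

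Gene lists were tested with camera in limma 3.58.1 on voom weights, with a preset correlation of 0.01 between members and Benjamini-Hochberg adjustment over the 23 lists of a comparison. Of these, 20 lists with 362 members were written down gene by gene, and all members were in the table. A further 3 were taken from the annotation: chloroplast-encoded genes, mitochondrion-encoded genes and 3910 gene models typed as pseudogenes, which stand in for transposon remnants because the annotation used did not name transposon genes. Of 253 list tests over all comparisons, 78 passed with the preset correlation. With a correlation estimated from the libraries, 0 of the 253 passed in camera, and the smallest adjusted p was 0.0658. Members past the threshold were counted over all genes and adjusted over the list alone.

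Named genes followed a rule, except HEI10, named because it overlaps MRD1, and some in the closing observations. The rule took ATR in every sample, and up to 4 members of each list with at least 3 members past the threshold or a list test past it. It also took the 8 largest log2 fold changes in each direction. Those came from genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups. A gene that met this rule is not reported here, though counts of genes and list tests include it. The groups, tests, lists, this rule and the alternatives were chosen before the data were examined. The alternatives were RLE scaling, no filter on low counts, a stricter filter of at least 10 counts in at least 4 libraries, an adjusted p below 0.01, a 2-fold minimum, DESeq2 1.42.0, the replicate number as a block, fits of the 24 h or 5 d libraries alone, fits of the compared groups alone, camera with an estimated correlation, and each library left out in turn. A fit without both atr MMC libraries was chosen after seeing the data. Overlaps between comparisons that share mock libraries were set beside 20 simulations of unchanged groups.

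The tests were run first on simulated counts drawn from the means and library sizes of the 19317 gene models, with 100 genes changed 2-fold and 100 changed 4-fold. For WT MMC against WT mock, 69% of the 2-fold and 90% of the 4-fold changes were recovered. The shares were 76% and 93% for WT zebularine against WT mock at 24 h, and 47% and 82% for the zebularine by genotype interaction. In 10 simulated runs with no change, no comparison gave more than 5 genes, and 8 of 110 comparisons had a list past the threshold. Simulated genes were drawn independently, each with the same dispersion in every group. They carry no correlation between list members and no wider spread in any group. These shares therefore set no error rate for the list tests in the real libraries.

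Names, products, neighbouring and overlapping genes and upstream sequence came from NCBI RefSeq's TAIR10.1 annotation, to which 31912 gene models matched by identifier. No coordinates are printed, because the annotation behind the table is not given in the sources used here. Overlap with another gene model was found for 63 of 263 named genes, and for 17 the largest overlap covered at least 20% of the gene. Reads in such overlaps cannot be assigned where the strand is unknown, so SDC, MRD1, ERF105, PP2-B13, AT3G01830, SUVH6, LUX, MYBR1, COR15B, TUB1, TCH3, GPX7, EXT3, PGDH, AT1G23110, AT1G47860 and AT3G27360 are uncertain. The same holds for near-identical families whose reads the counting could split: histones H3.1 and H4, RBCS, LHCB1 and LHCB2, VSP1 and VSP2, PP2-B13 and PP2-B14, and MBP1 and MBP2.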

Results

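RNA-seq read counts were measured in dissected shoot apices of Arabidopsis thaliana, in 16 libraries that form 8 groups of 2. Wild-type (WT) plants and atr-2 mutants, which lack a working copy of the checkpoint kinase gene ATR, were kept on mock medium, on 20 µM zebularine for 24 h or on 10 µM mitomycin C (MMC) for 24 h. Further WT plants spent 5 days on mock medium or on 20 µM zebularine. Zebularine is a cytidine analogue that inhibits DNA methylation, and MMC crosslinks DNA strands. The comparisons ask which transcripts changed with each drug, whether those changes differed without ATR, and how 24 h of zebularine compared with 5 days. Total counts ran from 12069182 to 16362311 in the WT libraries of the 24 h set and from 6746970 to 13771856 in the atr libraries. They ran from 9074597 to 18265411 in the 5-day set. Chloroplast-encoded genes held 0.019% to 0.049% of a library's counts and mitochondrion-encoded genes 0.008% to 0.025%. The chloroplast share was 0.045% and 0.024% in WT MMC replicates 1 and 2, and 0.019% and 0.035% in those of atr MMC. Shifts of these lists may therefore reflect differences between libraries. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 3.91 in WT mock, 7.18 in WT MMC and 16.14 in atr MMC. Levels are CPM, read counts scaled to library size, as mean ± SD (n = 2), and fold changes are log2 values with an approximate SE back-calculated from edgeR's F-test. The mock plants of the 24 h set are labelled with an exposure time of 0, and the labels do not say that they were harvested together with the treated plants. Nor do they say that replicates were separate pools of plants, so p-values measure the spread between these samples, which may be technical.

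ATR (AT5G40820) transcript was lower in every atr library than in every WT library. It ranged from 8.06 to 10.05 CPM in the 10 WT libraries and from 1.33 to 2.41 CPM in the 6 atr libraries. In atr mock it was 1.41 ± 0.117 CPM against 9.32 ± 0.596 CPM in WT mock, a log2 fold change of -2.73 (SE 0.19, edgeR adjusted p = 1.26e-05). No treatment moved it past the threshold in either genotype. The plot of CPM by library shows ATR with 5 genes named further on.

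**Figure D1:**
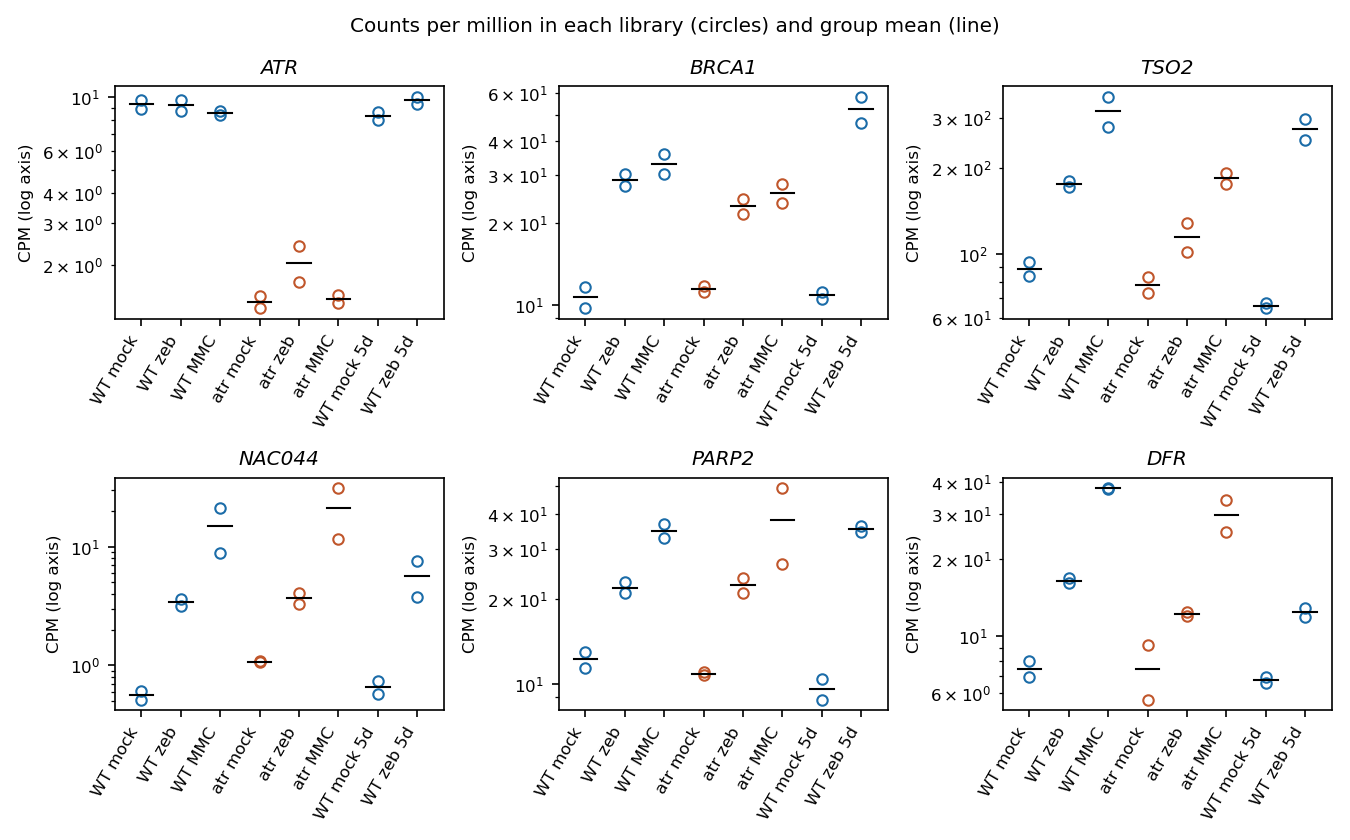
CPM on a log axis for ATR, BRCA1, TSO2, NAC044, PARP2 and DFR in the 8 groups, with 1 circle per library, a line at the group mean, WT in blue and atr in orange. ATR stays between 1.33 and 2.41 CPM in the atr libraries, and BRCA1 rises from a mean of 10.7 CPM in WT mock to 28.8 with zebularine.

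Before any drug, atr apices carried more transcript of some genes known from defence and wounding than WT apices. WRKY33, a transcription factor of defence against fungi, stood at 336 ± 43.9 CPM in atr mock against 42.4 ± 8.37 in WT mock (log2 fold change 2.99, SE 0.42). WRKY40, a regulator induced by pathogens, differed by 3.23 (SE 0.51), the lipoxygenase gene LOX4 of jasmonate synthesis by 4.75 (SE 0.55) and the peroxidase gene PER4 by 5.12 (SE 0.65). Of 20 salicylate and pathogen defence genes, 4 were higher (4 adjusted over the list alone), among them WRKY18 and EDS1. The pathogenesis-related genes PR1 and PR2, on the same list, were not among the 4. The median of that list was 0.39 (camera adjusted p = 0.00252, and adjusted p = 0.652 with an estimated correlation). In the wounding, touch and jasmonate list, which was fixed as a marker of dissection, 4 of 15 genes were higher and 2 lower (10 and 3 adjusted over the list alone). Their median was 1.28 (camera adjusted p = 0.00109, and adjusted p = 0.624 with an estimated correlation). Its members moved apart: the calmodulin-like genes CML37 (4.77, SE 0.94) and TCH3 (1.74, SE 0.28) were higher, while the vegetative storage protein gene VSP2 (-1.47, SE 0.37) and LOX2 (-1.11, SE 0.27) were lower. None of the 25 DNA damage response genes tested passed in edgeR, and the list had a median of -0.04 (camera adjusted p = 0.802).

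Among genes lower in atr mock, the defensin gene PDF1.2 fell by 4.04 (SE 0.76) and the cold and abscisic acid gene RAB18 fell by 1.79 (SE 0.43). MRD1 had 0 counts in atr mock against 131 in WT mock, where it stood at 4.58 ± 0.406 CPM, so it was at least 16.1-fold lower against a floor of 3 counts per library. MRD1 had 1 count over all 6 atr libraries. Gene models on the opposite strand overlap it, by up to 86.8% of its length, and HEI10, a meiotic crossover gene, is among them. HEI10 fell by 1.78 (SE 0.24), and reads in the overlap cannot be assigned without strand. It stood at 1.81 to 3.2 CPM in the atr libraries and at 5.23 to 8.91 CPM in the WT libraries. The xylem protease genes XCP1 (-0.61, SE 0.12) and XCP2 (-0.53, SE 0.14) fell, as 2 of the trichome and vascular genes (6 adjusted over the list alone). Median change in that list was -0.32 (camera adjusted p = 0.00448, and adjusted p = 0.624 with an estimated correlation). Smaller list shifts without a member past the threshold were seen for photosynthesis (median -0.24, camera adjusted p = 0.00126), G2/M genes (0.11, adjusted p = 0.00497), histones (0.14, adjusted p = 0.0299) and chloroplast-encoded genes (0.31, adjusted p = 0.00448). All 4 had an adjusted p = 0.652 with an estimated correlation. By edgeR's quasi-likelihood test, 465 genes were higher and 275 lower in atr mock, 740 in all, and 319 and 53 of them differed at least 2-fold. That count was 69 without WT mock replicate 1, 152 without WT mock replicate 2, 223 without atr mock replicate 1 and 282 without atr mock replicate 2, and 250 to 1662 over the other settings. PER4, LOX4, MRD1 and ATR, of 26 named genes, passed whichever library was left out. List calls ended for photosynthesis and G2/M without atr mock replicate 2 (adjusted p = 0.18 and 0.293), for trichome and vascular genes without atr mock replicate 1 (0.0535). Histones (0.0869 and 0.404) and chloroplast genes (0.159 and 0.17) lost theirs in camera without WT mock replicate 1 or atr mock replicate 2.

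After 24 h of zebularine, WT apices had higher transcript of BRCA1, TSO2, RNR1 and TK1a. BRCA1 (AT4G21070), a homologous recombination gene, rose from 10.7 ± 1.36 to 28.8 ± 2.07 CPM (log2 fold change 1.42, SE 0.14, edgeR adjusted p = 0.00234). TSO2 (AT3G27060), the small subunit of ribonucleotide reductase, rose from 88.8 ± 6.74 to 176 ± 5.89 CPM (0.99, SE 0.14), its large subunit RNR1 by 0.76 (SE 0.12) and the thymidine kinase gene TK1a by 1.07 (SE 0.13). Of 25 DNA damage response genes, 2 rose (14 adjusted over the list alone), and the list's median was 0.76 (camera adjusted p = 8.79e-11, and adjusted p = 0.117 with an estimated correlation). Of 21 DNA replication genes, 1 rose (15 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 1.56e-13, and adjusted p = 0.117 with an estimated correlation). In the anthocyanin list, DFR (1.15, SE 0.18) and LDOX (1.1, SE 0.18), enzymes of the pigment pathway, were the 2 of 14 that rose (8 adjusted over the list alone). The list's median was 0.76 (camera adjusted p = 7.93e-09, and adjusted p = 0.117 with an estimated correlation). The asparaginase gene ASPGB1 rose by 1.48 (SE 0.24), the glutathione transferase gene GSTU20 by 0.95 (SE 0.13), and COR15B, a cold-induced chloroplast protein gene, fell by 1.61 (SE 0.21).

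Other lists moved in that comparison with 0 members past the edgeR threshold over all genes. The clock list, a marker of harvest time, had a median of -0.27 (camera adjusted p = 0.000535; 2 lower adjusted over the list alone, and adjusted p = 0.117 with an estimated correlation). In it, the light-input gene FKF1 was at -1.49 (edgeR adjusted p = 0.0786). Salicylate genes had a median of 0.53 (camera adjusted p = 0.00635; 1 higher adjusted over the list alone, and adjusted p = 0.614 with an estimated correlation), and PR2, a pathogenesis-related glucanase, was at 2.02. Histones had a median of 0.13 (adjusted p = 0.00303) and abscisic acid and cold genes one of -0.48 (adjusted p = 0.011; 2 lower adjusted over the list alone), both at adjusted p = 0.412 with an estimated correlation. Photosynthesis genes, which mark leaf tissue, had a median of -0.15 (camera adjusted p = 0.0323, and adjusted p = 0.785 with an estimated correlation). In all, 14 genes rose and 3 fell by edgeR's quasi-likelihood test, 17 in total, and 7 and 2 of them by at least 2-fold, while 2721 had an unadjusted p below 0.05. The total of 17 was 2 without WT mock replicate 1, 1 without WT zebularine replicate 1 and 0 without either replicate 2, so none of the 12 named genes passed whichever library was left out. Over the other settings it ran from 1 to 853, with 268 in DESeq2. Calls ended for photosynthesis without WT mock replicate 2 (adjusted p = 0.38), for salicylate without WT zebularine replicate 1 (0.159), and for photosynthesis, histones and abscisic acid genes without WT zebularine replicate 2 (0.499, 0.0664 and 0.499).

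MMC for 24 h moved 2897 genes in WT apices, some DNA damage, defence and pigment genes among them. NAC044 (AT3G01600), a transcription factor of the plant DNA damage response, rose from 0.561 ± 0.0677 to 15.0 ± 8.63 CPM (log2 fold change 4.74, SE 0.62, edgeR adjusted p = 0.000831). SMR7, a cell cycle inhibitor, rose by 4.08 (SE 0.52). Of 25 DNA damage response genes, 19 rose (22 adjusted over the list alone), among them XRI1 (1.86, SE 0.19), TSO2 (1.84, SE 0.14) and BRCA1 (1.62, SE 0.14). The list's median was 1.17 (camera adjusted p = 9.87e-15, and adjusted p = 0.0658 with an estimated correlation). Among replication genes 13 of 21 rose (14 adjusted over the list alone), with RNR1 at 0.94 (SE 0.12), the polymerase gene TIL1 at 0.80 (SE 0.10) and the helicase subunit gene MCM3 at 0.61 (SE 0.09). Their median was 0.52 (camera adjusted p = 3.54e-10, and adjusted p = 0.209 with an estimated correlation). Anthocyanin genes rose in 11 of 14 cases (12 adjusted over the list alone), such as DFR (2.34, SE 0.17) and LDOX (1.94, SE 0.17). Their median was 1.46 (camera adjusted p = 3.98e-13, and adjusted p = 0.0658 with an estimated correlation).

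Some defence genes rose with MMC in WT, although their libraries lay far apart. PR1, a marker of the salicylate response, stood at 0.263 ± 0.264 CPM in WT mock and at 79.1 and 10.7 CPM in the MMC libraries (log2 fold change 7.28, SE 1.18, edgeR adjusted p = 0.0021). PR2 rose from 1.90 to 21.6 ± 8.82 CPM (3.52, SE 0.89). Of 20 salicylate genes, 8 rose (13 higher and 1 lower adjusted over the list alone), and the median was 1.14 (camera adjusted p = 1.9e-05, and adjusted p = 0.395 with an estimated correlation). In the detoxification list 5 of 20 rose (10 adjusted over the list alone), among them UPOX (2.28, SE 0.46), a mitochondrial oxidative stress gene, and the glucosyltransferase gene UGT74E2 (1.27, SE 0.29). The median was 0.67 (camera adjusted p = 7.27e-05, and adjusted p = 0.356 with an estimated correlation). Genes without a list included AT2G18193, an AAA-type ATPase gene, at 5.93 (SE 0.87), and AT5G60250, a zinc finger protein gene, at 4.16 (SE 0.67).

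Lower transcripts with MMC in WT included some clock, photosynthesis and flowering genes. The clock and photosynthesis lists were fixed as markers of harvest time and leaf tissue. Both had lower medians in camera in all 4 comparisons of a drug with mock at 24 h, where the mocks are labelled with an exposure of 0. Camera adjusted p was 0.000535 and 9.64e-05 for clock genes with zebularine and MMC in WT, and 7.14e-05 and 0.000144 in atr. With an estimated correlation these stood at adjusted p = 0.117, 0.0658, 0.0947 and 0.132. The clock repressor gene PRR5 fell from 52.5 to 10.3 CPM (log2 fold change -2.35, SE 0.28), and FKF1 fell by 2.57 (SE 0.33). Of 12 clock genes, 7 fell (8 adjusted over the list alone; median -0.67, camera adjusted p = 9.64e-05, and adjusted p = 0.0658 with an estimated correlation). Of 22 photosynthesis genes, 7 fell (13 adjusted over the list alone), such as the photosystem I subunit gene PSAF (-0.66, SE 0.13). Their median was -0.43 (camera adjusted p = 2.13e-06, and adjusted p = 0.515 with an estimated correlation). The floral regulators SVP (-0.37, SE 0.08), SOC1 (-0.52, SE 0.12) and SPL9 (-0.41) were the 3 of 12 flowering genes that fell (4 adjusted over the list alone). The median of the list was -0.45 (camera adjusted p = 0.0338, and adjusted p = 0.209 with an estimated correlation). AT2G33830, a dormancy and auxin associated gene, fell by 3.53 (SE 0.34), and the asparagine synthetase gene ASN1 (-2.81, SE 0.35) and the dark-induced gene SEN1 (-2.68, SE 0.34) fell too. EdgeR's quasi-likelihood test called 1528 genes higher and 1369 lower, 2897 in all, and 283 and 164 of them at least 2-fold. The count was 1179 without WT mock replicate 1, 672 without WT mock replicate 2, 964 without WT MMC replicate 1 and 1606 without WT MMC replicate 2. Without WT mock replicate 2 more genes fell (348) than rose (324). Of 55 named genes 29 passed in edgeR, NAC044, SMR7, XRI1, TSO2, BRCA1, PR1, DFR, PRR5 and FKF1 among them, whichever library was left out. With an adjusted p limit of 0.01 it was 1017, and the flowering call ended without WT mock replicate 1 (camera adjusted p = 0.0816) or WT MMC replicate 2 (0.0705).

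Set directly against each other in WT, zebularine left DFR, PR1, TSO2 and UGT74E2 lower than MMC did, at different doses of 20 and 10 µM. DFR differed by a log2 value of -1.19 (SE 0.16, edgeR adjusted p = 0.00766), PR1 by -5.08 (SE 0.95), TSO2 by -0.85 (SE 0.13) and UGT74E2 by -1.60 (SE 0.30). AT2G33830 (1.70, SE 0.33) and BT5, a BTB and TAZ domain protein gene (1.23, SE 0.21), were higher with zebularine. In the anthocyanin list 4 genes were lower (8 adjusted over the list alone), with a median of -0.66 (camera adjusted p = 4.01e-13, and adjusted p = 0.0818 with an estimated correlation). Of the damage response genes 1 was lower (11 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 3.84e-11, and adjusted p = 0.106 with an estimated correlation). Detoxification genes had a median of -0.65 (1 lower, 8 adjusted over the list alone, camera adjusted p = 1.18e-08, and adjusted p = 0.156 with an estimated correlation). Salicylate genes had one of -0.41 (1 lower, 3 adjusted over the list alone, camera adjusted p = 0.00013, and adjusted p = 0.497 with an estimated correlation). With 0 members past the edgeR threshold, medians were higher with zebularine for clock (0.43, 5 adjusted over the list alone, camera adjusted p = 0.00295) and flowering genes (0.35, 3 adjusted over the list alone, adjusted p = 0.00558). Both had an adjusted p = 0.106 with an estimated correlation. The same held for photosynthesis (0.29, 1 adjusted over the list alone, camera adjusted p = 1e-06, and adjusted p = 0.543 with an estimated correlation) and histone genes (0.15, adjusted p = 0.0015, and adjusted p = 0.345 with an estimated correlation). Replication genes had a lower median (-0.11, camera adjusted p = 0.0301, and adjusted p = 0.824 with an estimated correlation).

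Of these direct differences, 49 genes were higher and 22 lower with zebularine by edgeR's quasi-likelihood test, 71 in all. The count was 2 without WT zebularine replicate 1, 0 without WT zebularine replicate 2, 1 without WT MMC replicate 1 and 33 without WT MMC replicate 2. With the compared groups alone it turned to 123 higher and 151 lower. It stood beside 2505 genes at an unadjusted p below 0.05 and 226 in DESeq2, and none of 19 named genes passed whichever library was left out. The replication call ended without WT zebularine replicate 2 (camera adjusted p = 0.247) or WT MMC replicate 1 (0.763). Against their shared mock libraries, both drugs raised 13 genes and lowered 3, where independent lists would share 1.11 and 0.213. Unchanged groups simulated against the same mocks shared 0 and 0.05, but few of their genes pass at all, so this sets no bound on what the shared mocks add to lists of this length. Fold changes across genes had a correlation of 0.667, against 0.503 simulated, and a covariance of 0.1421, against 0.0419. Part of the overlap may come from the shared mocks. These mocks are labelled with an exposure of 0, so time on the plates and harvest time may add to it too. That total of 16 was 2 without WT mock replicate 1, 1 without WT zebularine replicate 1, 8 without WT MMC replicate 1 and 0 without replicate 2 of WT mock or of WT zebularine.

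In atr apices, 24 h of zebularine raised BRCA1, TK1a, XRI1 and MCM3 and lowered a larger set of genes with BT2 near its head. BRCA1 rose from 11.5 ± 0.351 to 23.1 ± 2.08 CPM (log2 fold change 1.02, SE 0.15, edgeR adjusted p = 0.015), TK1a by 1.11 (SE 0.15), XRI1 by 1.07 (SE 0.20) and MCM3 by 0.47 (SE 0.09). BT2, a BTB and TAZ domain gene linked to nitrogen and sugar signals, fell from 140 ± 47.3 to 27.9 CPM (-2.34, SE 0.23). AT2G20670 (-2.09, SE 0.24), the senescence regulator NAC092 (-1.86, SE 0.36) and SEN1 (-1.69, SE 0.32) fell as well. Of the damage response genes, 2 rose (7 adjusted over the list alone; median 0.56, camera adjusted p = 2.66e-07, and adjusted p = 0.324 with an estimated correlation). Of the replication genes 1 rose (9 adjusted over the list alone; median 0.32, camera adjusted p = 3.83e-08, and adjusted p = 0.324 with an estimated correlation). Of the anthocyanin genes TT19, a glutathione transferase of pigment transport, rose by 0.88 (3 adjusted over the list alone). The list's median was 0.36 (camera adjusted p = 0.0243, and adjusted p = 0.536 with an estimated correlation). An overlap with AT5G17230 on the opposite strand covers 8.7% of TT19. That neighbour held 53160 counts over all libraries against 2326 for TT19, so the rise of TT19 is uncertain.

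With 0 members past the edgeR threshold in that comparison, the clock list had a median of -0.56 (4 lower adjusted over the list alone, camera adjusted p = 7.14e-05, and adjusted p = 0.0947 with an estimated correlation). In it the morning gene LHY was at -1.26. Photosynthesis genes had a median of -0.26 (camera adjusted p = 1.27e-05, and adjusted p = 0.573 with an estimated correlation). Medians were above 0 for histones (0.18, camera adjusted p = 7.14e-05, and adjusted p = 0.324 with an estimated correlation) and G2/M genes (0.10, adjusted p = 0.0412, and adjusted p = 0.644 with an estimated correlation). They were also above 0 for DNA methylation machinery (0.11, camera adjusted p = 0.0412, and adjusted p = 0.573 with an estimated correlation). Meristem genes had 2 higher adjusted over the list alone, STM and AS2 not past the edgeR threshold, and a median of 0.17 (adjusted p = 0.0412, and adjusted p = 0.474 with an estimated correlation). In all 24 genes rose and 99 fell by edgeR's quasi-likelihood test, 123 in total, and 6 and 41 of them by at least 2-fold. The total was 2 without atr mock replicate 1 and 15 without atr zebularine replicate 1, with 6 to 1005 over the other settings, and BT2 and AT2G20670, of 17 named genes, passed whichever library was left out. Without atr mock replicate 1 the calls for photosynthesis (camera adjusted p = 0.0571), G2/M (0.796), methylation machinery (0.399) and meristem genes (0.399) ended. Without atr zebularine replicate 1 so did those in camera for methylation machinery (0.684), meristem (0.285) and anthocyanin genes (0.285), and G2/M turned lower (0.396). The anthocyanin call ended without atr mock replicate 2 (0.107). Both genotypes shared 3 raised genes and 1 lowered gene with zebularine, where independent lists would share 0.0174 and 0.0154. Mocks of both genotypes are labelled with an exposure of 0, so time on the plates and harvest time may add to this overlap. That total of 4 was 2 without WT mock replicate 1, 1 without WT zebularine replicate 1 and 0 without either replicate 2 of these groups. On the atr side it was 0 and 2 without mock replicates 1 and 2, and 1 and 7 without zebularine replicates 1 and 2.

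MMC in atr apices raised damage response and pigment genes and lowered some photosynthesis and clock genes. NAC044 rose from 1.07 CPM to 11.5 and 31.2 CPM in the libraries (log2 fold change 4.31, SE 0.58, edgeR adjusted p = 0.000556). Of the 25 damage response genes, 18 rose (20 adjusted over the list alone), such as PARP2, a poly(ADP-ribose) polymerase (1.81, SE 0.22), XRI1 (1.78, SE 0.19) and BRCA1 (1.17, SE 0.15). The median was 1.07 (camera adjusted p = 6.99e-13, and adjusted p = 0.139 with an estimated correlation). Replication genes rose in 9 of 21 cases (11 adjusted over the list alone; TIL1 0.81, SE 0.11), with a median of 0.38 (camera adjusted p = 5.35e-07, and adjusted p = 0.369 with an estimated correlation). Anthocyanin genes rose in 8 of 14 cases (9 adjusted over the list alone; DFR 1.97, SE 0.18), with a median of 0.88 (camera adjusted p = 4.15e-06, and adjusted p = 0.173 with an estimated correlation). Detoxification genes rose in 5 of 20 cases (6 adjusted over the list alone; UPOX 2.49, SE 0.45), with a median of 0.61 (camera adjusted p = 0.000884, and adjusted p = 0.473 with an estimated correlation). In the wounding and jasmonate list VSP1 (3.13, SE 0.40), VSP2 (2.60, SE 0.37) and LOX2 (1.86, SE 0.27) rose, while ERF105 (-1.42, SE 0.42) and the touch gene TCH4 (-1, SE 0.31) fell. That list had 3 higher and 3 lower adjusted over the list alone (median -0.59, camera adjusted p = 0.582). Heat shock genes HSP70-4 (1.70, SE 0.43) and HSP90.1 (1.69, SE 0.42) rose, 2 of 7 members (3 adjusted over the list alone; median 1.14, camera adjusted p = 0.0899). Salicylate genes had 1 higher and 1 lower (median -0.06, camera adjusted p = 0.54).

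Among genes that MMC lowered in atr were AT2G20670 (-3.47, SE 0.26), BT2 (-3.45, SE 0.24), AT2G15020 (-3.40, SE 0.63) and BT5 (-3.14, SE 0.24). RBCS2B, a Rubisco small subunit gene, fell by 1.58 (SE 0.20). Of 22 photosynthesis genes, 8 fell (13 adjusted over the list alone; median -0.41, camera adjusted p = 4.14e-08, and adjusted p = 0.473 with an estimated correlation). Clock genes fell in 5 of 12 cases (5 adjusted over the list alone; RVE8 -1.15, SE 0.19; CCA1 -1.22, SE 0.27), with a median of -0.65 (camera adjusted p = 0.000144, and adjusted p = 0.132 with an estimated correlation). G2/M genes fell in 5 of 31 cases (6 adjusted over the list alone), such as CDC20.2, an activator of mitotic exit (-0.49, SE 0.11), and the cyclin gene CYCB1;4 (-0.43, SE 0.11). Their median was -0.21 (camera adjusted p = 0.00254, and adjusted p = 0.52 with an estimated correlation). SVP, SOC1 and FD were the 3 flowering genes that fell (4 adjusted over the list alone; median -0.39, camera adjusted p = 0.0148, and adjusted p = 0.173 with an estimated correlation). Of 50 chloroplast-encoded genes 4 fell (0 adjusted over the list alone in edgeR), with a median of -0.58 (camera adjusted p = 0.000134, and adjusted p = 0.52 with an estimated correlation). By edgeR's quasi-likelihood test 1436 genes rose and 1520 fell, 2956 in all, and 196 and 341 of them at least 2-fold. The count was 753 without atr mock replicate 1, 1572 without atr mock replicate 2 and 1342 without atr MMC replicate 2, and 880 when only the compared groups were fitted. In edgeR 33 of 65 named genes, NAC044, XRI1, PARP2, BRCA1, DFR, BT2, BT5, RBCS2B and VSP1 among them, passed whichever library was left out. Calls ended for G2/M (camera adjusted p = 0.0826) and flowering (0.105) without atr mock replicate 2, for chloroplast genes without atr MMC replicate 1 (0.189), and for flowering (0.13) and detoxification (0.0544) without atr MMC replicate 2.

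Within atr, zebularine and MMC shared 20 raised and 97 lowered genes, where independent lists would share 1.78 and 7.79. Simulated unchanged groups shared 0 and 0.05, which again sets no bound for lists of this length. The correlation of fold changes was 0.588 against 0.501 simulated and their covariance 0.1487 against 0.0493, and part of the overlap may come from the shared mocks. That total of 117 was 2 without atr mock replicate 1, 13 without atr zebularine replicate 1, 314 without atr MMC replicate 1 and 248 without atr MMC replicate 2. Across genotypes, MMC raised 830 and lowered 677 genes in both, against 114 and 108 for independent lists, with 13 in opposite directions and a correlation of fold changes of 0.435 across genes, which are not independent replicates. BRCA1, NAC044 and DFR were raised in both. Every comparison of a drug with mock at 24 h uses mocks labelled with an exposure of 0. Time on the plates and harvest time may therefore add to each of these overlaps. The total of 1507 was 799 and 467 without WT mock replicates 1 and 2, 713 and 899 without WT MMC replicates 1 and 2, 500 and 862 without atr mock replicates 1 and 2, and 763 without atr MMC replicate 2.

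**Figure D2:**
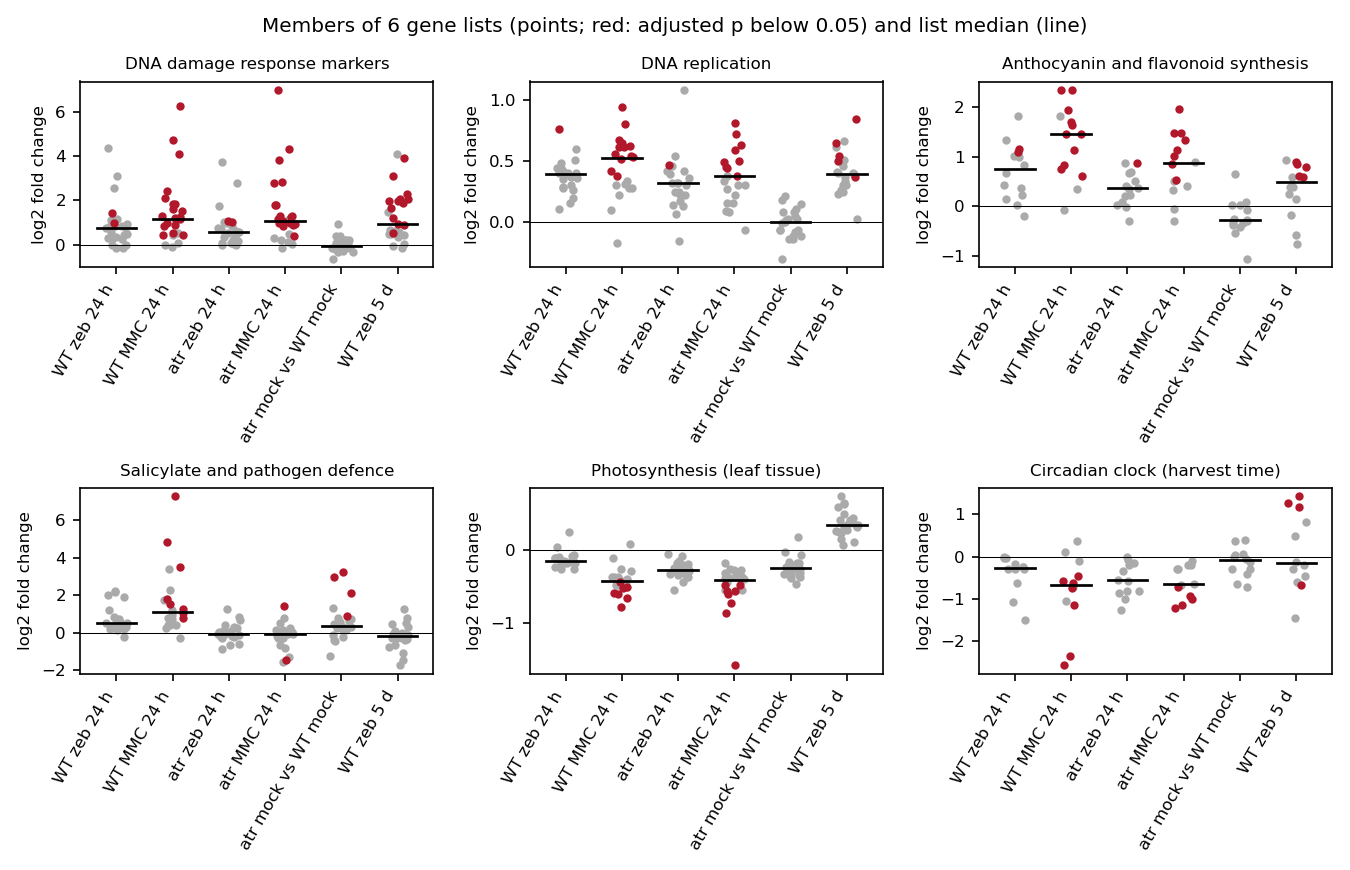
Log2 fold changes of the members of 6 gene lists (DNA damage response, replication, anthocyanin, salicylate, photosynthesis and clock) in 6 comparisons, with 1 point per gene, red where the adjusted p was below 0.05 and a line at the median. The damage response list has a median of 1.17 with MMC in WT and 1.07 in atr, and the salicylate list one of 1.14 in WT and -0.06 in atr.

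The test of whether zebularine acted differently without ATR called 7 genes, all at an edgeR adjusted p of 0.0485. PORA, an enzyme of chlorophyll synthesis, went from 15.7 to 7.88 CPM in WT and from 8.47 to 13.5 CPM in atr (difference of log2 fold changes 1.67, SE 0.25). COR15B, which overlaps another gene, gave 2.06 (SE 0.31). TEM1 (-2.14, SE 0.33) and RAV1 (-1.88, SE 0.26), related repressors of flowering and growth, AT3G19680 (-2.38, SE 0.37), AT2G20670 (-2.03, SE 0.31) and ARL, a gene of organ growth (-1.44, SE 0.22), had a lower response in atr. TEM1 went from 54.4 to 75.8 CPM in WT and from 36.8 to 11.8 CPM in atr. With 0 members past the edgeR threshold, salicylate (median -0.50, camera adjusted p = 0.0274) and anthocyanin genes (-0.28, 0.0318) had lower responses in atr. Abscisic acid and cold genes (1.18, camera adjusted p = 0.00207) and gene models typed as pseudogenes (0.12, 0.0219) had higher ones, and all 4 had an adjusted p = 0.837 with an estimated correlation. The damage response list did not pass (median -0.21, camera adjusted p = 0.478), with BRCA1 at -0.41 (SE 0.21) and TSO2 at -0.42 (SE 0.19). The count of 7 in edgeR was 0 without any library of WT mock or WT zebularine and without replicate 1 of atr mock or atr zebularine, 16 without atr mock replicate 2, 19 without atr zebularine replicate 2 and 2 with the 24 h libraries alone. It stood beside 1162 genes at an unadjusted p below 0.05 and 46 in DESeq2. All 4 list calls ended in some of these fits. Salicylate lost its call without replicate 1 of WT mock (camera adjusted p = 0.0821), WT zebularine (0.338), atr mock (0.224) or atr zebularine (0.148). Anthocyanin did so without WT mock replicate 1 (0.0821), WT zebularine replicate 2 (0.0547), atr mock replicate 1 (0.272) or atr zebularine replicate 2 (0.274). Abscisic acid genes did so without WT zebularine replicate 2 (0.103) or atr mock replicate 1 (0.0571). Pseudogene models did so without WT mock replicate 2 (0.0516), WT zebularine replicate 1 (0.363), atr mock replicate 1 (0.0571) or atr zebularine replicate 2 (0.06).

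For MMC, the test of the genotype difference called 9 genes with a higher and 33 with a lower response in atr. VSP1 went from 7.23 ± 0.569 to 63.6 ± 1.32 CPM in atr, against 18.1 ± 6.37 CPM in WT mock (difference of log2 fold changes 2.99, SE 0.55, edgeR adjusted p = 0.0476). CORI3, a jasmonate-induced gene, gave 2.31 (SE 0.32). The ethylene response factor genes DREB26 (-3.57, SE 0.53) and ERF2 (-2.69, SE 0.39), the brassinosteroid gene BEE3 (-2.20, SE 0.25), BT5 (-2.16, SE 0.32) and EXO, a cell growth gene (-2.13, SE 0.26), had lower responses in atr. Salicylate genes had a median of -1.60 (camera adjusted p = 2.51e-07; 0 members past the edgeR threshold, 3 lower adjusted over the list alone, and adjusted p = 0.596 with an estimated correlation). The salicylate median was -0.899 without WT MMC replicate 1 and -2.143 without WT MMC replicate 2. PR2 was at 2.22 CPM in atr mock and 2.26 CPM in atr MMC. PR1 was at 0.498 and 0.460 CPM, and its difference of -7.28 (SE 3.11) did not pass. In the other lists that passed, 0 members passed in edgeR, over all genes or adjusted over the list alone. Anthocyanin genes had a median difference of -0.41 (camera adjusted p = 0.000562) and abscisic acid and cold genes one of 1.25 (0.00324), both at adjusted p = 0.596 with an estimated correlation. The median difference of responses was below 0 for G2/M (-0.15, camera adjusted p = 0.00971, and adjusted p = 0.681 with an estimated correlation) and chloroplast genes (-0.58, 0.000848, and adjusted p = 0.681 with an estimated correlation). It was above 0 for trichome and vascular genes (0.32, camera adjusted p = 0.0361, and adjusted p = 0.624 with an estimated correlation), whose median in atr mock against WT mock was -0.32. Damage response genes did not differ past the threshold (median 0.03, camera adjusted p = 0.645); NAC044 gave -0.43 (SE 1.01), XRI1 -0.08 (SE 0.27) and BRCA1 -0.45 (SE 0.21).

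That count of 42 genes with a genotype-dependent MMC response was 0 and 5 without WT mock replicates 1 and 2, 5 and 23 without WT MMC replicates 1 and 2, 0 without atr mock replicate 1, and 125 and 74 without atr MMC replicates 1 and 2. In edgeR 1693 genes lay at an unadjusted p below 0.05, and DESeq2 called 144. Of 16 named genes, VSP1, DREB26 and BEE3 among them, none passed whichever library was left out. The chloroplast call ended without WT MMC replicate 1 (camera adjusted p = 0.407), atr mock replicate 2 (0.0617) or atr MMC replicate 1 (0.58). The G2/M call ended without replicate 2 of WT mock (0.0538), WT MMC (0.0726), atr mock (0.273) or atr MMC (0.0682), and that of trichome and vascular genes without WT mock replicate 2 (0.0904), WT MMC replicate 2 (0.0726), atr mock replicate 1 (0.184) or atr MMC replicate 1 (0.433).

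The drugs also differed from each other within atr. UPOX (-2.46, SE 0.47), NAC044 (-2.55, SE 0.50), GMI1, a gene induced by DNA breaks (-2.18, SE 0.35, edgeR adjusted p = 0.0176), and DFR (-1.28, SE 0.17) were lower with zebularine than with MMC. RBCS2B (1.15, SE 0.20), BT5 (1.71, SE 0.26) and the mitotic gene CDC20.2 (0.72, SE 0.11) were higher. Of the lists, damage response had 5 lower (11 adjusted over the list alone; median -0.54, camera adjusted p = 7.17e-09, and adjusted p = 0.18 with an estimated correlation). Detoxification had 4 lower (10 adjusted over the list alone; median -0.72, camera adjusted p = 9.21e-07, and adjusted p = 0.211 with an estimated correlation) and anthocyanin 1 lower (8 adjusted over the list alone; -0.58, 3.55e-06, and adjusted p = 0.18 with an estimated correlation). G2/M had 3 higher (8 adjusted over the list alone; median 0.24, camera adjusted p = 5.93e-09, and adjusted p = 0.187 with an estimated correlation). Flowering had 1 higher (4 adjusted over the list alone; median 0.47, camera adjusted p = 4.53e-05, and adjusted p = 0.0832 with an estimated correlation) and photosynthesis 1 higher (0.17, 6.52e-05, and adjusted p = 0.537 with an estimated correlation). With 0 members past the edgeR threshold, histones had a median of 0.28 (camera adjusted p = 3.79e-07, and adjusted p = 0.18 with an estimated correlation). Chloroplast-encoded genes had one of 0.74 (camera adjusted p = 7.17e-09) and mitochondrion-encoded genes one of 0.63 (camera adjusted p = 0.00363), again with 0 past it. Both stood at adjusted p = 0.358 with an estimated correlation. They held only 0.019% and 0.008% of the counts in atr MMC replicate 1, and 0.035% and 0.023% in replicate 2. By edgeR's quasi-likelihood test 92 genes were higher and 118 lower with zebularine, 210 in all, with none of 25 named genes past it whichever library was left out. The count was 14 without atr zebularine replicate 2, 623 without atr MMC replicate 1 and 1 without atr MMC replicate 2, and in edgeR 0 when only these groups were fitted, beside 3138 at an unadjusted p below 0.05 and 342 in DESeq2. More genes were higher than lower without atr zebularine replicate 1 (113 and 49) or atr MMC replicate 1 (337 and 286), and as many without atr zebularine replicate 2 (7 and 7). List calls ended for mitochondrion genes without atr MMC replicate 1 (camera adjusted p = 0.285) and for photosynthesis without atr MMC replicate 2 (0.895).

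After 5 days of zebularine, WT apices had higher transcripts of damage response genes than their 5-day mock. BRCA1 rose from 10.8 ± 0.484 to 52.4 ± 8.29 CPM (log2 fold change 2.29, SE 0.14, edgeR adjusted p = 5.15e-06) and TSO2 from 66.1 ± 1.97 to 273 ± 32.4 CPM (2.05, SE 0.14). PARP2 rose by 1.90 (SE 0.22). Of 25 damage response genes, 13 rose (22 adjusted over the list alone; median 0.96, camera adjusted p = 2.28e-15, and adjusted p = 0.175 with an estimated correlation). Of 21 replication genes 5 rose (15 adjusted over the list alone; median 0.40, camera adjusted p = 8.08e-10, and adjusted p = 0.322 with an estimated correlation). Anthocyanin genes rose in 5 of 14 cases (6 adjusted over the list alone; DFR 0.89, SE 0.19), with a median of 0.49 (camera adjusted p = 0.00054, and adjusted p = 0.41 with an estimated correlation). Of 10 genes silenced by DNA methylation, SDC and QQS were the 2 with enough counts to test, and both rose (2 adjusted over the list alone; median 2.75, camera adjusted p = 0.00887, and adjusted p = 0.289 with an estimated correlation). SDC went from 4 to 42 counts over 2 libraries (3.56, SE 0.56), though 67.8% of it overlaps AT2G17695, and QQS from 26 to 88 (1.94, SE 0.46). Among members with too few counts to test, PHE1 went from 15 to 5 counts and MPC from 6 to 1. EVD went from 3 to 8, FWA and HDG3 from 0 to 2, and ATMU1, FIS2 and HDG9 stayed at 0. The list call thus rests on SDC and QQS alone and does not describe the whole list. MET1, the maintenance DNA methyltransferase gene, rose by 0.47 (SE 0.10) and VIM3 by 0.53 (SE 0.13), as 2 of 27 methylation machinery genes (7 higher and 3 lower adjusted over the list alone; median 0.10, camera adjusted p = 0.183).

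Clock genes went both ways at 5 days. CCA1 (1.18, SE 0.27), LHY (1.26, SE 0.29) and PRR9 (1.42, SE 0.27), expressed towards morning, rose, and the evening gene TOC1 fell by 0.68 (SE 0.13) in the edgeR test. Of the 12 clock genes, 3 rose and 1 fell (5 higher and 3 lower adjusted over the list alone), and the list's median was -0.16 and its mean 0.113 (camera adjusted p = 0.983). Photosynthesis genes had a median of 0.35 with 0 past the edgeR threshold (3 higher adjusted over the list alone, camera adjusted p = 2.29e-06, and adjusted p = 0.668 with an estimated correlation). AT2G15020 rose by 4.74 (SE 0.56), AT4G22960 by 4.11 (SE 0.62) and AT3G09450 by 3.22 (SE 0.40), while AT4G16870, typed as a pseudogene, changed by -1.81 (SE 0.15). AT5G03545 fell from 85.6 ± 27.6 to 2.69 ± 0.965 CPM (-4.90, SE 0.60), as did the noncoding RNA gene IPS1 (-6.00, SE 1.54) and the lipid synthesis gene MGDC (-3.96, SE 0.93), both known to be induced by phosphate starvation. IPS1 stood at 21.0 and 2.28 CPM in the mock libraries, which lay far apart. Other DNA repair genes had LIG1 and SMC6A higher and FAN1, XRCC1 and ATM lower (2 higher and 4 lower adjusted over the list alone; median 0.12, camera adjusted p = 0.638). By edgeR's quasi-likelihood test 644 genes rose and 429 fell, 1073 in all, and 133 and 103 of them at least 2-fold. The count was 163 and 301 without mock replicates 1 and 2, and 200 and 333 without zebularine replicates 1 and 2, with 222 to 2523 over the other settings. Without mock replicate 2 more genes fell (177) than rose (124). In edgeR 12 of 44 named genes, BRCA1, TSO2, PARP2, AT2G15020 and AT5G03545 among them, passed whichever library was left out. Without mock replicate 2 the calls for silenced genes (camera adjusted p = 0.0591) and anthocyanin genes (0.117) ended.

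Between 24 h and 5 days the zebularine response differed in 159 genes, with 113 higher and 46 lower at 5 days. The mocks are labelled with an exposure of 0 in the 24 h set and of 5 days in the 5-day set. This contrast therefore cannot separate a change of the drug response from time on the plates or harvest time in the 24 h set. TSO2 had a response greater by 1.06 (SE 0.19, edgeR adjusted p = 0.0237), while BRCA1 at 0.86 (SE 0.20) did not pass (adjusted p = 0.0667). AT2G15020 (6.15, SE 0.69), AT3G09450 (4.09, SE 0.52) and PRR5 (1.89, SE 0.36) were higher, and AT5G03545 (-4.59, SE 0.89), AT3G19680 (-3.28, SE 0.31), EXO (-2.46, SE 0.24) and MYB51, a regulator of glucosinolate synthesis (-2.44, SE 0.43), lower. EXO went from 43.6 to 80.8 CPM at 24 h and from 194.5 to 64.6 CPM at 5 days. Of the lists, damage response had 1 higher (3 adjusted over the list alone; median 0.27, camera adjusted p = 0.00117). Photosynthesis had a median of 0.49 (camera adjusted p = 1.29e-08) and clock 2 higher (5 adjusted over the list alone; 0.35, 0.0207). These 3 lists stood at adjusted p = 0.565 with an estimated correlation. Salicylate genes had a median of -0.90 (camera adjusted p = 0.0207, and adjusted p = 0.896 with an estimated correlation). The count of 159 in edgeR was 66 and 14 without WT mock replicates 1 and 2, 62 and 18 without WT zebularine replicates 1 and 2, 34 and 40 without the 5-day mock replicates, and 20 and 85 without the 5-day zebularine replicates, in that order. Higher and lower genes were then equal in number without WT mock replicate 2 (7 and 7), 5-day mock replicate 2 (20 and 20) or 5-day zebularine replicate 1 (10 and 10). Of 21 named genes AT2G15020, AT3G09450, AT3G19680, EXO, BME3 and AT2G47440 passed whichever library was left out. The damage response call ended without 5-day zebularine replicate 2 (camera adjusted p = 0.0619), the clock call without WT zebularine replicate 1 (0.0611) or 5-day mock replicate 2 (0.0712). The salicylate call ended without replicate 1 of WT mock (0.0619), WT zebularine (0.163), 5-day mock (0.226) or 5-day zebularine (0.168).

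The 24 h and 5-day zebularine comparisons, which share no library, had 7 raised and 2 lowered genes in common, against 0.467 and 0.0666 for independent lists. BRCA1, TSO2, RNR1, DFR and LDOX were raised at both times. That total of 9 was 2 and 0 without WT mock replicates 1 and 2, 1 and 0 without WT zebularine replicates 1 and 2, and 5 without 5-day mock replicate 2. WT MMC and 5-day zebularine had 117 raised and 75 lowered genes in common, against 50.9 and 30.4 for independent lists. A further 156 went in opposite directions, 32 higher and 124 lower with MMC, against 33.9 and 45.6, and the correlation of fold changes across genes was -0.02. The total of 192 was 87 and 69 without WT mock replicates 1 and 2, 82 without WT MMC replicate 1, 37 and 52 without the 5-day mock replicates, and 62 and 38 without the 5-day zebularine replicates, in that order.

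Lists that passed camera in no comparison included other DNA repair genes, cell death and senescence, root tissue and heat shock. With MMC in WT, SMC6B (0.47) and SNI1 (0.95), which act in chromosome maintenance, rose among 4 other DNA repair genes, and XRCC1 (-0.39, SE 0.12) fell. Of the 32 tested, 4 rose and 1 fell (4 higher and 1 lower adjusted over the list alone; median 0.14, camera adjusted p = 0.172). Cell death genes came closest with zebularine in WT (median -0.25, camera adjusted p = 0.058), and heat shock genes in the contrast of the drugs within atr (median -1.49, adjusted p = 0.0506). PYK10, a root and endoplasmic reticulum body gene, rose by 0.69 (SE 0.14) at 5 days, the 1 of 5 root genes to pass (edgeR adjusted p = 0.0154), and the list's lowest camera adjusted p was 0.0724. Methylation machinery genes DDM1 (0.60) and CMT3 (0.40) rose with MMC in WT and SUVH6 (-0.52, SE 0.09), which overlaps another gene, fell (median 0.17, camera adjusted p = 0.0571). Of 133 gene models typed as pseudogenes, 3 rose and 5 fell with MMC in WT (median -0.10, camera adjusted p = 0.303) and 5 rose and 5 fell with zebularine at 5 days (median -0.10, adjusted p = 0.269).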

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

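The tests on genes higher in atr mock, on clock genes at 5 days, on the mock and zebularine levels of genes with a lower MMC response and on the levels of genes with a higher one were chosen only after the results they bear on were seen; those on the levels with MMC of the genes with a lower response and of the salicylate list, and on single WT MMC libraries, were not. The differences of response in the next 3 paragraphs were picked out because edgeR's or camera's test of the difference itself, between genotypes or between times, passed its threshold.

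For zebularine, the response differed between WT and atr in 7 genes, and in 0 to 19 with 1 library left out. The difference of log2 fold changes, atr minus WT, was 2.06 for COR15B, 1.67 for PORA, -2.38 for AT3G19680, -2.14 for TEM1, -2.03 for AT2G20670 and -1.88 for RAV1. By list, the median difference was -0.50 for salicylate, -0.28 for anthocyanin, 1.18 for abscisic acid and cold genes and 0.12 for gene models typed as pseudogenes. All 4 had an adjusted p = 0.837 with an estimated correlation.

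For MMC, the response differed between genotypes in 42 genes. The difference, atr minus WT, was 3.23 for AT4G17470, 2.99 for VSP1, 2.31 for CORI3, 1.65 for MBP1, -3.57 for DREB26, -2.69 for ERF2, -2.60 for AT2G20670 and -2.35 for AT5G54710. Median differences were -1.60 for salicylate, -0.41 for anthocyanin, -0.15 for G2/M, 0.32 for trichome and vascular, 1.25 for abscisic acid and cold and -0.58 for chloroplast-encoded genes. With an estimated correlation these lists stood at adjusted p = 0.596 (salicylate, anthocyanin, abscisic acid and cold), adjusted p = 0.624 (trichome and vascular) and adjusted p = 0.681 (G2/M, chloroplast). For the 9 genes with a higher response, the median log2 difference between atr and WT was -1.198 in mock, and 7 passed the edgeR threshold. With MMC it was 0.583, with 4 past it. Both are parts of the contrast that picked these genes. With zebularine, outside that contrast, the median was 0.004, with 5 of 9 higher, inside the -0.211 to 0.192 of matched random lists. A lower level in atr mock therefore stays open as a source of their higher response.

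Between 24 h and 5 days, the zebularine response differed in 159 genes. Mocks of the 24 h set are labelled with an exposure of 0, so time on the plates and harvest time cannot be separated from the drug response there. The difference, 5 days minus 24 h, was 6.15 for AT2G15020, 4.09 for AT3G09450, 4.04 for AT3G28270, 3.54 for AT3G24420, -4.59 for AT5G03545, -3.28 for AT3G19680, -2.46 for EXO and -2.44 for MYB51. Median differences were 0.27 for damage response, -0.90 for salicylate, 0.49 for photosynthesis and 0.35 for clock genes. With an estimated correlation salicylate stood at adjusted p = 0.896 and the other 3 at adjusted p = 0.565.

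The 465 genes higher in atr mock than in WT mock, WRKY33 and LOX4 among them, may reflect the state of the atr mock libraries, the genotype or a difference in handling between genotypes. Their median log2 difference between atr and WT was 1.079 with zebularine and 0.676 with MMC, beside 1.395 in mock. Random lists matched on expression had an upper bound of at most 0.036. Such lists lack the correlation between members, so that bound may be too narrow. Of the 465 genes, 301 passed the edgeR threshold in the same direction with zebularine and 140 with MMC. These values argue against the state of the atr mock libraries as the whole cause for these genes. How far the genotype alone accounts for them stays open. Of the mock difference, 77.3% was kept with zebularine (bootstrap interval 71.9 to 83) and 48.5% with MMC (43.7 to 52.4), on either side of the 50% set for it. The bootstrap drew genes and not libraries, so its intervals do not measure the spread between libraries. Picking the genes by their mock difference also raises that difference and so lowers the share kept. The wounding, touch and jasmonate list, fixed as a marker of dissection, moved with them (median 1.284, camera adjusted p = 0.00109, and adjusted p = 0.624 with an estimated correlation), with 10 of 15 members higher and 3 lower adjusted over the list alone. The labels do not say that the genotypes were grown or dissected together, so handling stays open beside the genotype.

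The lower MMC response of 33 genes in atr, DREB26 and ERF2 among them, and of the salicylate list could come from raised levels in atr mock. For the 33 genes the median log2 difference between atr and WT was -0.212 in mock, with 13 of them higher. The mock pair is part of the contrast that picked the genes, and that choice pushes its value up. A median below 0 despite this argues against raised mock levels as the whole cause for these genes. The -1.726 with MMC is part of the same contrast and decides nothing. The -1.376 with zebularine, with 23 genes past the edgeR threshold, comes from libraries outside that contrast. For the salicylate list the median difference was 0.393 in mock, above the upper bound of 0.111 in matched random lists. Raised mock levels therefore stay open for this list. Its -0.643 with MMC, below the 2.5% bound of -0.112, is part of the contrast that flagged the list and does not decide this. With zebularine, outside that contrast, it was -0.271, below a bound of -0.13, with 0 members past the edgeR threshold. Random lists do not carry the correlation between members. A single WT MMC library is argued against for the salicylate list, because its median interaction was -0.899 without replicate 1 and -2.143 without replicate 2. A dependence of these levels on ATR under either drug remains a hypothesis, and a difference in handling or harvest time between genotypes stays open.

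Clock genes at 5 days moved by phase: the mean log2 change was 1.085 in 4 dawn-phased genes, CCA1, LHY, RVE8 and PRR9, and -0.600 in 6 dusk-phased ones, a difference of 1.685. The genes were split by phase after they had been seen to go both ways, so the split supports neither another time of day at harvest of the treated plants nor a clock shifted by zebularine, and both stay open as candidate explanations. Library size is argued against, since total counts of the groups overlapped, at a ratio of means of 0.876. At 24 h the clock list was lower in camera with either drug in either genotype, against mocks labelled with an exposure of 0. Camera adjusted p ran from 7.14e-05 to 0.000535, and from 0.0658 to 0.132 with an estimated correlation. By phase the genotypes differed. With MMC the dawn and dusk means were -0.194 and -1.001 in WT, and -0.9 and -0.351 in atr. With zebularine they were -0.152 and -0.487 in WT, and -0.76 and -0.405 in atr. Harvest time therefore stays open at 24 h as well, also as a difference between the treated plants of the 2 genotypes.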

How the results depend on the processing

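The fit without both atr MMC libraries was chosen only after the data were seen; the others were not. Counting depth limited genes with few reads, such as SDC with 4 counts in 5-day mock. With each library left out in turn, the lone library of its group is assumed to vary like the other groups; single genes kept their direction and side of the threshold in 1660 cases, lost the call in 768, gained it in 8 and turned in 4, and lists kept it in 302 cases, lost it in 65 and turned in 1. Under an estimated correlation all 78 list calls were lost, under DESeq2 7, with no filter 5 and with only the compared groups 6, and under RLE, the stricter filter or the replicate block none of 78. RLE scaling and the stricter filter moved no total of genes past the threshold in a comparison by more than 1.5 times. Except where a construction is named, the cause was not tested.

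The ranges with 1 library left out were, in genes, 0 to 2 for WT zebularine at 24 h, 672 to 1606 for WT MMC, 2 to 140 for atr zebularine, 753 to 3525 for atr MMC, 69 to 282 for atr against WT mock and 163 to 333 for zebularine at 5 days. They were 0 to 19 for zebularine by genotype, 0 to 125 for MMC by genotype, 14 to 85 for zebularine by time, 0 to 33 for WT zebularine against MMC and 1 to 623 for atr zebularine against MMC. Genes shared in direction ranged over 0 to 16 for both drugs in WT, 2 to 314 for both in atr, 0 to 7 for zebularine in both genotypes, 467 to 1949 for MMC in both, 0 to 8 for zebularine at both times and 37 to 155 for MMC and 5-day zebularine. For WT zebularine 24 h vs WT mock, ATR ranged from -0.089 to 0.06, with 0.053 without WT mock replicate 1 and 0.06 without WT zebularine replicate 2, against -0.02 over all libraries. For atr MMC 24 h vs atr mock, ATR ranged from -0.038 without atr mock replicate 1 to 0.11, with -0.023 without atr MMC replicate 1, against 0.05. ATR did not pass in either. For atr zebularine 24 h vs atr mock, list G2/M cell cycle ranged from a signed -log10 p of -0.402 without atr zebularine replicate 1 to 4.06.

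At an adjusted p below 0.01, edgeR called 1 gene for WT zebularine, 1017 for WT MMC, 6 for atr zebularine, 1139 for atr MMC, 250 for atr mock, 222 for zebularine at 5 days. It called 0 for zebularine by genotype (1162 at an unadjusted p below 0.05), 1 for MMC by genotype, 25 for zebularine by time, 10 for WT zebularine against MMC and 1 for atr zebularine against MMC. Shared genes were 1 for both drugs in WT, 6 for both in atr, 0 for zebularine in both genotypes, 485 for MMC in both, 1 for zebularine at both times and 32 for MMC and 5-day zebularine. With a 2-fold minimum added, in the order WT zebularine, WT MMC, atr zebularine, atr MMC, atr mock and 5 days, the counts were 9, 447, 47, 537, 372 and 236, with 101 for zebularine by time, 28 for the drugs in WT and 54 in atr. Both are stricter by construction.

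With no filter on low counts, 25109 genes were tested and the prior degrees of freedom went from 5.66 to 84.66. Counts were 853 for WT zebularine, 1005 for atr zebularine, 1662 for atr mock, 2523 at 5 days, 237 for zebularine by genotype, 661 for MMC by genotype, 1046 for zebularine by time, 875 for the drugs in WT and 1004 in atr. DESeq2 gave 268 for WT zebularine, 307 for atr zebularine, 46 and 144 for zebularine and MMC by genotype, 272 for zebularine by time, 226 for the drugs in WT and 342 in atr. Shared genes were 253 for both drugs in WT, 278 in atr, 35 for zebularine in both genotypes and 52 at both times. Fitting only the compared groups gave 796 for WT zebularine, 880 for atr MMC, 1637 for atr mock, 19 for zebularine by genotype, 566 for zebularine by time, 274 for the drugs in WT and 0 in atr (3138 at an unadjusted p below 0.05 over all groups). The 24 h libraries alone gave 48 for atr zebularine, 2 for zebularine by genotype, 21 for the drugs in WT and 110 in atr. Without both atr MMC libraries the counts were 224 for WT zebularine, 368 for atr zebularine, 1757 at 5 days, 382 for zebularine by time and 271 for the drugs in WT, with a biological coefficient of variation of 0.086 against 0.098.

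With the replicate number as a block, edgeR called 71 genes for atr zebularine, 0 for zebularine by genotype (1162 at an unadjusted p below 0.05 without the block, and 46 in DESeq2), 24 for MMC by genotype and 30 for the drugs in WT, and other counts moved by less than 1.5 times. The pairing check gave correlations of deviations from -0.173 to 0.479 over 28 pairs of groups, 6 above 0.1 and 5 below -0.1. The labels do not say what libraries of the same number share, so the numbers were not treated as pairs. A pseudocount was not varied, because the values are counts, and zebularine by time could not be fitted within the 24 h or 5-day libraries alone.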

Other observations

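Of the choices here, AT1G59359 and the genes named among those moving in opposite directions were chosen only after their values were seen; the tests of the upstream motif were not.

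Among the 156 genes that WT MMC and 5-day zebularine moved in opposite directions, 124 were lower with MMC and higher at 5 days, where independent lists would give 45.6. They included BT5 (-0.98, SE 0.21, and 2.24, SE 0.21), the clock-regulated gene RVE1 (-1.33 and 1.77), EPR1 (-0.77 and 1.23) and the ferric reductase genes FRO6 (-1.15 and 1.03) and FRO7 (-1.05 and 1.55), all in log2 fold changes from edgeR. In the other direction 32 genes were higher with MMC and lower at 5 days, against 33.9. These included the galactolipid synthase gene MGD2 (1.44, SE 0.30, and -1.77, SE 0.33), the sulfolipid gene SQD1 (0.65 and -0.62), PHF1, a phosphate transporter traffic factor (0.44 and -0.47), PHO1;H1 (0.70 and -1.04) and PLDP2 (1.72 and -1.84). No list of phosphate or iron genes was fixed, so no theme was tested, and the difference in exposure time goes with the difference in drug. Photosynthesis genes, a marker of leaf tissue, had a median of -0.43 with MMC (camera adjusted p = 2.13e-06, and adjusted p = 0.515 with an estimated correlation) and 0.35 at 5 days (2.29e-06, and adjusted p = 0.668 with an estimated correlation). Clock genes, a marker of harvest time, had a median of -0.67 with MMC (camera adjusted p = 9.64e-05, and adjusted p = 0.0658 with an estimated correlation) and -0.16 at 5 days (0.983), and the mocks of the MMC comparison are labelled with an exposure of 0.

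AT1G59359, a ribosomal protein S2 family gene with near-identical copies, stood at 38.7 CPM in WT mock 5 d replicate 2 and at no more than 0.849 CPM in the other 15 libraries. Reads shared between copies cannot be placed from the counts.

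SOG1, the transcription factor of the plant DNA damage response, is known to bind CTT(N)7AAG, so a hypothesis was that genes at least 2-fold higher carry it within 500 bp upstream more often than other tested genes. With WT MMC 19.8% of 283 genes carried it against 17.1% of the others, an odds ratio of 1.2 (95% interval 0.88 to 1.62, Fisher's exact test, p = 0.233, 0.705 adjusted over 18 tests). With zebularine at 5 days 22.6% of 133 genes carried it, an odds ratio of 1.42 (0.91 to 2.15, Fisher's exact test, p = 0.105, 0.582 adjusted), so neither set met the prediction. In atr MMC the odds ratio was 1.58 (1.11 to 2.21, Fisher's exact test, p = 0.00752), which did not pass after adjustment (0.135).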
